A study of Homo sapiens with 7 samples.

How the data were processed

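The authors deposited a table of raw counts per gene symbol, which per the file headers has 1 column for each of the 7 libraries and was used here without change. The authors also deposited a table of log values, normalised between libraries by the authors with a transform and a base that the sources used here do not name. The authors' deposited table of the DJL1 and CTRL comparison gives log2 fold changes and, per the file headers, a p-value and an adjusted p-value for each gene, with a filter that the sources used here do not give. The same deposited table holds, per the file headers, a t statistic and a log odds score for each gene, and these scores were not used. The submitters' processing notes name Trim Galore 0.4.0, HISAT2 2.2.1 and featureCounts of Subread 1.5.0 with the builds GRCh38 and hg38, without giving the role or order of each. The library kit is directional and selects poly(A) RNA, but the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Each column of the deposited log table correlated best with its own library of the count table over 13766 genes (r of 0.996 to 0.997, slope 0.635 to 0.641 against log2 CPM), a check of the column names across genes that are not independent replicates. A plain log2 table would have a slope near 1, so its base and transform stay unsettled, and no result uses its values.

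The 7 libraries form 2 groups, CTRL (n = 4) and DJL1 (n = 3), read from the sample titles. The labels do not say whether the replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical. The labels give no batch. They mention cell sorting in the treatment while the design text has cells taken directly for RNA, so whether the cells were sorted is unclear. Of 59251 rows, 57842 matched a RefSeq symbol of GRCh38.p14, the source of gene positions and gene types, and 26062 passed edgeR's filterByExpr (minimum count 10, minimum total 15) and held 99.9% of the counts. Counts were scaled by TMM factors, and DJL1 was compared with CTRL by edgeR's quasi-likelihood test with robust dispersion, 2-sided, with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken from the fold change and the F statistic. Values are given as mean ± SD in CPM, counts per 1000000 counts of the library scaled by the same factors, and log2 CPM uses a prior count of 2. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15, with transcript lengths and GC content from GENCODE release 29.

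Lists of genes were tested with limma's camera on voom values with a preset correlation of 0.01 against all other tested genes, with Benjamini-Hochberg adjustment over the 24 of 25 lists with at least 5 tested members. Of these, 20 were called, 11 higher and 9 lower. With a correlation estimated from the data 0 of the 24 were called by camera, whereas fry, which does not compare a list with other genes, called 21. Beside each count over all tested genes stands the count adjusted over the list alone. The medians of the lists were also set against 10000 random lists matched on mean expression. Named genes were chosen by a rule. It takes the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM in a group, no overlap between the groups and a symbol that is not a clone, antisense, readthrough or pseudogene name. It adds up to 4 members of each list with the smallest adjusted p, and NCL, NPM1, FBL, TRIM28, POU5F1, NANOG, SOX2, KLF17, DPPA3, CDKN1A, MDM2 and UBTF in any case, 126 genes in all. Genes of chromosomes 13, 14, 15, 21 and 22 were compared with those of other autosomes by Fisher's exact test. The groups, the test, the 25 lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be chosen after.

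The alternatives were DESeq2, limma-voom, relative log expression factors, upper quartile factors, library size alone, no filter, a stricter filter (1 CPM in at least 3 libraries), counts thinned to the smallest library, removal of the gene length trend, an adjusted p of 0.01, each library left out in turn and the replicate number as a block. Chosen after the data were seen were voom with a variance for each group, protein-coding genes alone, the same with the trend of GC content and transcript length removed, the matched random lists, and for single genes upper quartile factors, no filter, thinning and removal of the gene length trend. In simulated counts with 200 of 26062 genes changed, edgeR made 5 false calls (3.50% of its calls) with equal spread in both groups and 16 (10.9%) with the spread of each group. In the latter it recovered 56.7% of 1.5-fold, 58.2% of 2-fold and 81.8% of 4-fold changes, and DESeq2 made 67 false calls (33.0%). In the data 52.0% of tested genes were called, far more than were changed in the simulation, so these shares do not give the false share of the real calls. Of 24 random lists camera called 0 in simulated counts with equal spread and 2 with the spread of each group, and it called the list with planted changes in both (adjusted p = 1.6e-40 and 3.6e-17). The simulated genes were drawn independently, so these lists do not test whether the preset correlation is large enough. In the data the estimated correlation reached 0.61, for the cytosolic ribosomal protein genes.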

Results

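H9 human embryonic stem cells, an established pluripotent line, were kept in a naive-state medium (RSeT) and compared after transfection with guide RNA plasmids named DJL1 or as a control named CTRL. Per the labels both groups also received 10 nM DZNep, an inhibitor of histone methylation, 5 nM TSA, a histone deacetylase inhibitor, and for the initial 16 h the survival cocktail CEPT, so all values are from cells under these chromatin inhibitors. The series title places the study on LINE1 retrotransposons at the distal junctions of the ribosomal DNA repeats, sequences on the short arms of the acrocentric chromosomes that border the nucleolus organizer regions, and on nucleolar organization. The comparison asks which genes differ in steady-state poly(A) RNA between DJL1 and CTRL cells 48 h after transfection. The sources used here do not name the protein that the guides direct or what the CTRL cells received in their place, and RNA of the LINE1 elements themselves was not analysed here because the table counts genes. RNA-seq counts were read for 4 CTRL and 3 DJL1 libraries. Total counts ran from 62277489 to 76691997 in the CTRL libraries and from 34634882 to 37795742 in the DJL1 libraries, so the groups did not overlap in depth. The spread between libraries, which edgeR names the biological coefficient of variation but which may be technical here, was 3.46% within CTRL and 13.8% within DJL1. Depth and spread thus both differed with the group. Since no batch is given, a difference in library preparation or sequencing between the groups could not be told apart from an effect of the transfection. Pairs of libraries correlated across genes with a mean Pearson r of 0.993 within CTRL, 0.975 within DJL1 and 0.964 between the groups, and the leading principal component of the 500 most variable genes, with 62.2% of their variance, separated the groups.

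Interferon-response, p53-target and 8-cell-stage genes were higher in DJL1 cells, and genes for shared pluripotency factors, nucleolar proteins, ribosomal proteins and the cell cycle were mostly lower by smaller amounts. As lists, camera with a preset correlation called all of these among 20 of 24 lists, but called 0 of 24 with an estimated correlation (adjusted p = 0.153 to 0.419 for the lists just named), and fry called 21. Of 26062 genes tested, 7029 were higher and 6530 lower in DJL1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, together 52.0% of the genes tested. Changes of at least 2-fold were mostly increases, with 2791 genes higher and 573 lower. With a stricter filter these counts were 1659 and 235, in protein-coding genes alone, an alternative chosen after the data were seen, 1926 and 114, and at an adjusted p under 0.01 359 genes were lower by at least 2-fold. For 13973 genes (53.6%) no DJL1 value overlapped a CTRL value, which chance alone gives for 5.71% of genes. The median log2 fold change over all tested genes was 0.01. All values are shares of a scaled library, and TMM scaling centres the log ratios. A change in total RNA per cell therefore could not be seen. By expression, the median went from 0.23 over the 7831 genes under 1 CPM (counts per 1000000 counts of the library) to -0.12 over the 3590 genes above 64 CPM.

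**Figure D1:**
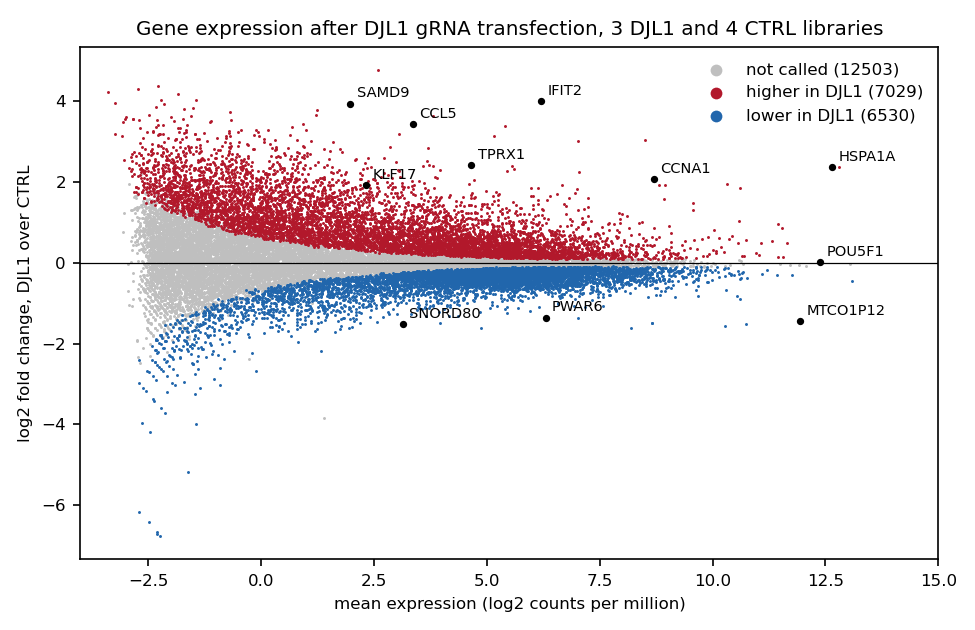
Log2 fold change of DJL1 over CTRL against mean expression in log2 CPM, 1 point per tested gene, red for the 7029 genes higher in DJL1, blue for the 6530 genes lower and grey for the others. Interferon-response genes such as IFIT2 (161 CPM in DJL1 against 10.1 CPM in CTRL) lie at the upper edge at moderate expression, and POU5F1 lies at 0.01.

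Members of the interferon list held 7 of the 10 highest fold changes among called genes with a group mean of at least 5 CPM and no overlap between the groups. All 23 tested members of the interferon list were higher in DJL1, and the same 23 were called when adjusted over the list alone. IFIT2, which encodes an RNA-binding antiviral protein, rose from 10.1 ± 1.35 CPM (SD, n = 4) in CTRL to 161 ± 14.6 CPM (SD, n = 3) in DJL1, a log2 fold change of 4.0 ± 0.09 (SE, adjusted p = 1.4e-12). IFIT1 and IFIT3, its neighbours on chromosome 10, rose by 3.38 and 3.15 on the log2 scale, although reads of these related genes can be split between them. IFIH1, the cytosolic sensor of long double-stranded RNA, rose from 2.52 ± 0.18 to 31.3 ± 4.06 CPM (log2 fold change 3.64 ± 0.10). The oligoadenylate synthetase genes OAS1 and OAS2, whose products activate RNase L, rose by 3.78 and 3.67 on the log2 scale, and the related OASL by 3.19. SAMD9, an interferon-induced restriction factor, rose from 0.64 ± 0.20 to 9.69 ± 1.30 CPM, and the chemokine gene CCL5 from 2.13 ± 0.72 to 22.8 ± 2.36 CPM. The more abundant ISG15, a ubiquitin-like modifier, and MX1, an antiviral GTPase, rose by 1.86 and 1.92. The median log2 fold change of the list was 1.92 (camera, adjusted p = 4.7e-16; adjusted p = 0.153 with an estimated correlation). The highest fold change among those 10 belonged to RNU6-1 on chromosome 15 (67839939 to 67840045, GRCh38.p14), a U6 spliceosomal RNA gene with many near-identical copies, at 0.56 ± 0.20 CPM in CTRL and 14.9 ± 6.04 CPM in DJL1 (log2 fold change 4.76 ± 0.30), and its count is uncertain for that reason.

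Targets of p53 and other stress genes were also higher. Of 25 tested p53 targets, 21 were higher and 1 lower, with 22 called when adjusted over the list alone. PLK2, a polo-like kinase gene, rose from 81.3 ± 4.24 to 246 ± 20.7 CPM (log2 fold change 1.60 ± 0.05), GDF15, a stress-induced cytokine gene, by 1.69, the ferredoxin reductase gene FDXR by 1.30 and the ribonucleotide reductase gene RRM2B by 1.18. CDKN1A, the cell cycle inhibitor p21, rose from 148 ± 2.82 to 286 ± 11.3 CPM (log2 fold change 0.95 ± 0.04), and MDM2, the ubiquitin ligase for p53, from 235 ± 7.94 to 463 ± 41.3 CPM (0.98 ± 0.05). The list's median log2 fold change was 0.98 (camera, adjusted p = 2.6e-14; adjusted p = 0.153 with an estimated correlation). In the integrated stress response list 13 of 22 members were higher and 2 lower, with 16 called when adjusted over the list alone, and the median was 0.38 (camera, adjusted p = 4.5e-05; adjusted p = 0.163 with an estimated correlation). The members with the smallest adjusted p were the transcription factor gene ATF3 (log2 fold change 1.32), the eIF2-alpha phosphatase subunit gene PPP1R15A (0.98), the mTORC1 inhibitor gene DDIT4 (0.89) and the sestrin gene SESN2 (0.76). Of 15 immediate early genes 14 were higher and none was lower, with 14 called when adjusted over the list alone, among them EGR2 (1.62), DUSP1 (0.78), JUN (0.69) and IER2 (0.44). Their median was 0.52 (camera, adjusted p = 4.6e-07; adjusted p = 0.179 with an estimated correlation).

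Genes of the 8-cell-stage embryo rose along with several naive markers, while core pluripotency factors stayed expressed at an unchanged or lower level. Of 25 tested 8-cell-stage genes 21 were higher and none was lower, with 22 called when adjusted over the list alone. The homeobox gene TPRX1 rose from 9.06 ± 1.22 to 48.5 ± 6.48 CPM (log2 fold change 2.42 ± 0.10), TPRX2 from 3.34 ± 0.60 to 14.2 ± 1.06 CPM, the phosphate transporter gene SLC34A2 from 6.53 ± 0.48 to 27.7 ± 7.48 CPM and the meiotic cyclin gene CCNA1 from 175 ± 15.1 to 738 ± 114 CPM. TPRX1 and TPRX2 are close relatives and may share reads, as may MBD3L2, MBD3L3 and MBD3L5. Outside the rule for named genes, several members lay near the floor, such as LEUTX (0.04 to 0.42 CPM) and PRAMEF1 (0.10 to 0.53 CPM from CTRL to DJL1). The 4 members not called were DUX4 (log2 fold change -0.49), H3Y2 (1.49), RFPL4B (1.42) and RFPL1 (1.05). The list's median was 2.08, against 0.13 for random lists matched on expression (camera, adjusted p = 7.2e-09; adjusted p = 0.184 with an estimated correlation). Of 19 naive pluripotency markers 14 were higher and 3 lower, with 17 called when adjusted over the list alone and a median of 0.93 (camera, adjusted p = 1.6e-05; adjusted p = 0.163 with an estimated correlation). KLF17, a transcription factor gene of the naive state and of the 8-cell list, rose from 2.48 ± 0.64 to 9.36 ± 3.37 CPM (log2 fold change 1.92 ± 0.23), and MAEL, KLF5, SUSD2 and KLF4 rose by 1.59, 1.14, 1.00 and 0.68. DPPA3, a maternal and naive-state factor gene, rose by 0.37. The 3 lower members, outside the rule for named genes, were FGF4 (-0.54), DPPA5 (-0.49) and TFCP2L1 (-0.21). OLAH (0.28) and TFAP2C (-0.03) were not called.

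Among 16 genes shared by naive and primed pluripotency none was higher and 12 were lower, with 14 called when adjusted over the list alone, 13 lower and 1 higher (UTF1, log2 fold change 0.27). POU5F1, which encodes OCT4, stood at 5324 ± 73.1 CPM in CTRL and 5354 ± 269 CPM in DJL1 (log2 fold change 0.01 ± 0.04, adjusted p = 0.879). NANOG fell from 121 ± 1.36 to 85.2 ± 7.66 CPM (log2 fold change -0.50 ± 0.05) and SOX2 from 321 ± 6.30 to 245 ± 15.6 CPM (-0.39 ± 0.04). The members with the smallest adjusted p were PRDM14 (-0.93), the embryonic stem cell RNA ESRG (-0.89), the telomere-binding factor gene TERF1 (-0.71) and DPPA4 (-0.66). The list's median was -0.40 (camera, adjusted p = 1.7e-06; adjusted p = 0.214 with an estimated correlation). Higher members numbered 2 at an unadjusted p under 0.05 in edgeR and 0 by DESeq2 and limma-voom. Primed markers went both ways, with 7 of 18 higher and 5 lower (13 called when adjusted over the list alone), and the list was not called (median 0.10, camera, adjusted p = 0.615). ZIC2 and ZIC5 rose by 2.01 and 1.55, whereas the de novo DNA methyltransferase gene DNMT3B had a log2 fold change of -0.83.

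Markers of later lineages, weakly expressed in CTRL, were higher in DJL1. In the interferon, 8-cell-stage, immediate early and germ layer lists, edgeR at an unadjusted p under 0.05, DESeq2 and limma-voom also called 0 members lower. Of 21 tested germ layer markers 20 were higher and none was lower, with 20 called when adjusted over the list alone and a median of 1.67 (camera, adjusted p = 6.9e-09; adjusted p = 0.153 with an estimated correlation). They included the mesenchymal factor FOXF1 (0.68 ± 0.11 to 4.32 ± 0.99 CPM), the homeobox gene MSX2 (4.99 ± 0.18 to 18.9 ± 3.66 CPM), the neural and eye factor PAX6 (2.25 ± 0.35 to 8.47 ± 0.74 CPM) and SOX9 (9.73 ± 0.86 to 20.7 ± 2.28 CPM). Of 17 trophectoderm markers 14 were higher and 1 lower, with 15 called when adjusted over the list alone and a median of 1.33 (camera, adjusted p = 1.7e-05; adjusted p = 0.163 with an estimated correlation). GATA3, a factor that specifies trophectoderm, rose from 1.53 ± 0.25 to 8.85 ± 0.78 CPM, and GATA2 and TBX3 rose by 1.90 and 1.33 on the log2 scale. Primitive endoderm markers were split. The transcription factor genes SOX17, GATA4 and GATA6 rose by 2.56, 2.49 and 1.21, the laminin gene LAMB1 had a log2 fold change of -0.38, and 7 of 14 were higher and 3 lower (11 called when adjusted over the list alone). That list was not called (median 0.37, camera, adjusted p = 0.174), and its median ran from 0.22 without DJL1 replicate 2 to 0.75 without DJL1 replicate 1. Fibroblast and feeder-cell markers, taken as a check for other cells, rose in 12 of 15 cases and fell in 1 case (13 called when adjusted over the list alone), with COL1A1 at 241 ± 5.41 and 484 ± 49.8 CPM, FN1 at 186 ± 4.84 and 292 ± 6.18 CPM, FBN1 at a log2 fold change of 1.29 and ACTA2 at 1.71. Their median was 0.59 (camera, adjusted p = 9.1e-05; adjusted p = 0.163 with an estimated correlation).

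**Figure D2:**
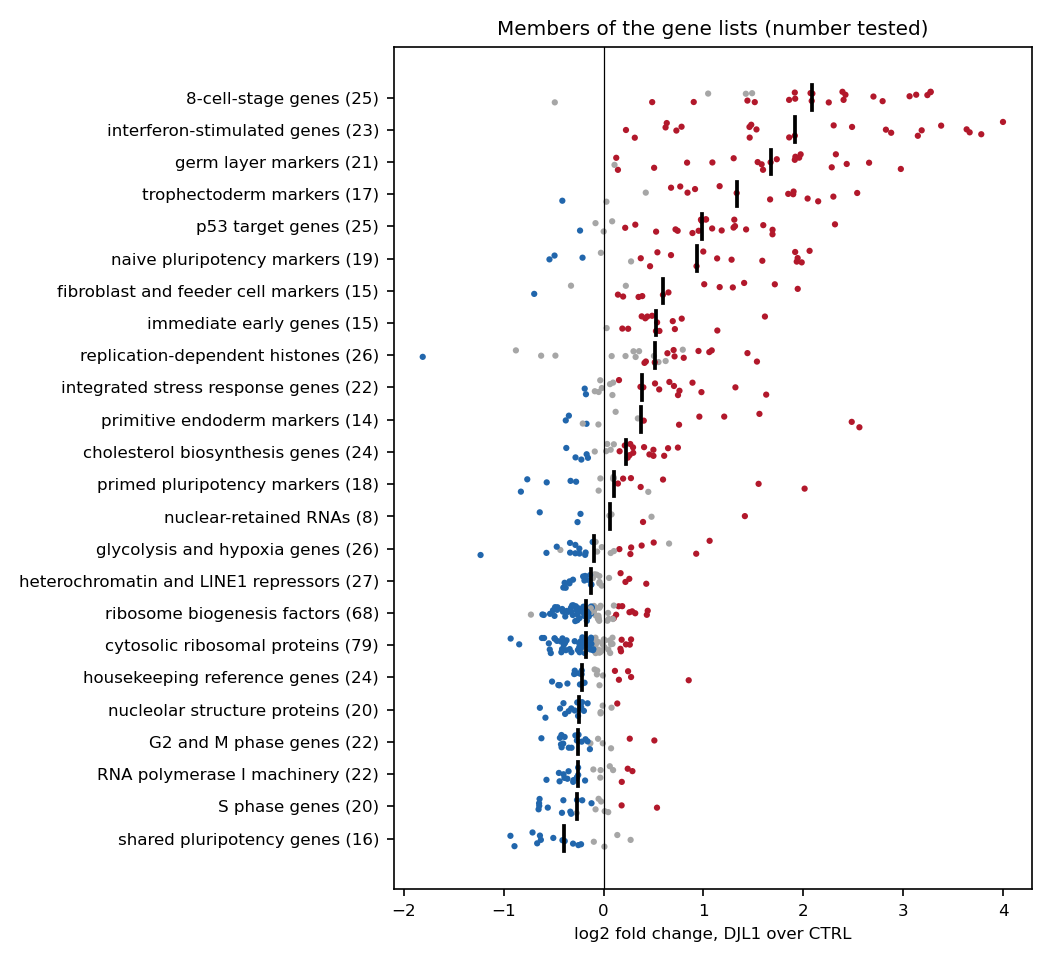
Log2 fold change of DJL1 over CTRL for every tested member of the 24 gene lists with tested members, red for higher, blue for lower and grey for not called, with the list median as a black bar and the number tested in brackets. All 23 interferon-stimulated genes lie above 0, and the medians run from 2.08 for 8-cell-stage genes to -0.40 for shared pluripotency genes.

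Nucleolar and ribosomal genes were mostly lower in DJL1, by small amounts, as were 14 of 24 housekeeping reference genes (median -0.21) and 51.4% of all tested genes above 64 CPM. NPM1, the granular-component protein nucleophosmin, fell from 1476 ± 20.4 to 1208 ± 60.2 CPM (log2 fold change -0.29 ± 0.04). Nucleolin (NCL) fell from 1602 ± 16.0 to 1380 ± 79.4 CPM (-0.22 ± 0.04) and fibrillarin (FBL) from 282 ± 5.64 to 246 ± 20.8 CPM (-0.20 ± 0.05). Of 20 nucleolar structure genes 15 were lower and 1 higher, with 16 called when adjusted over the list alone, among them NPM3 (-0.64), NOP10 (-0.58), NOP56 (-0.44) and GNL3 (-0.32). The median was -0.24, which lay at percentile 3.61 of random lists matched on expression (camera, adjusted p = 1.6e-05; adjusted p = 0.163 with an estimated correlation). Of 22 genes of the RNA polymerase I machinery 14 were lower and 3 higher, with 17 called when adjusted over the list alone. TAF1C and TAF1D, subunits of the promoter selectivity factor, had log2 fold changes of -0.57 and -0.44, the catalytic subunit genes POLR1A and POLR1B of -0.39 and -0.30, and the median was -0.26, at percentile 1.32 of matched random lists (camera, adjusted p = 0.0034; adjusted p = 0.163 with an estimated correlation). UBTF, the factor that binds the ribosomal DNA promoter, stood at 186 ± 3.22 and 182 ± 11.5 CPM (log2 fold change -0.03 ± 0.04, adjusted p = 0.595). Without DJL1 replicate 3 UBTF passed the test with a log2 fold change of -0.09 (adjusted p = 0.043), and over the other alternatives its adjusted p ran from 0.251 to 1.0. Of 68 ribosome biogenesis factors 40 were lower and 9 higher, with 54 called when adjusted over the list alone, including NOL11 (-0.61), EMG1 (-0.60), UTP4 (-0.54) and PWP2 (-0.51), factors of the small subunit processome. The median was -0.17, at percentile 6.77 of random lists matched on expression, which had a median of -0.11 (camera, adjusted p = 6.6e-06; adjusted p = 0.163 with an estimated correlation). Of 79 cytosolic ribosomal protein genes 47 were lower and 6 higher, with 53 called when adjusted over the list alone, including RPS13 (-0.60), RPS26 (-0.53), RPL35A (-0.49) and RPS3 (-0.43). The median was -0.18, at percentile 3.99 of matched random lists (camera, adjusted p = 8.3e-07; adjusted p = 0.419 with an estimated correlation). Many ribosomal protein genes have processed pseudogenes that can take part of their reads.

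Genes for heterochromatin and for repression of LINE1 elements changed little. Of 27 tested members 15 were lower and 4 higher, with 19 called when adjusted over the list alone and a median of -0.13, which lay at percentile 40.8 of random lists matched on expression (camera, adjusted p = 0.011; adjusted p = 0.237 with an estimated correlation). TRIM28, the KRAB zinc finger corepressor, fell from 1125 ± 14.8 to 985 ± 73.6 CPM (log2 fold change -0.19 ± 0.05). The HP1 genes CBX5 and CBX3 had log2 fold changes of -0.40 and -0.38 and UHRF1, which recruits maintenance DNA methylation, of -0.39, while MPHOSPH8, a subunit of the HUSH silencing complex, rose by 0.43. Cell cycle genes were lower. Of 20 S phase genes 12 were lower and 2 higher, with 15 called when adjusted over the list alone. The helicase genes MCM5 and MCM6 had log2 fold changes of -0.65 and -0.64, E2F1 of -0.65 and GINS2 of -0.64, and the median was -0.27 (camera, adjusted p = 7.4e-05; adjusted p = 0.184 with an estimated correlation). Of 22 G2 and M phase genes 16 were lower and 2 higher, with 19 called when adjusted over the list alone. CDK1, the mitotic kinase, had a log2 fold change of -0.62 ± 0.05, AURKB and TPX2 of -0.44 and -0.32, and CDC20, an activator of the anaphase-promoting complex, rose by 0.51. The median was -0.26 (camera, adjusted p = 5.3e-05; adjusted p = 0.163 with an estimated correlation). Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, were seen at low level, and 12 of 26 were higher and 1 lower (13 called when adjusted over the list alone), among them H4C8 (1.44), H2BC5 (0.95), H2BC8 (0.80) and H2BC12 (0.51). Their median was 0.51, at percentile 95.4 of random lists matched on expression, which had a median of 0.16 (camera, adjusted p = 0.0068; adjusted p = 0.163 with an estimated correlation).

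Genes of cholesterol synthesis were mostly higher, with 14 of 24 higher and 5 lower and 20 called when adjusted over the list alone. INSIG1, a sterol-responsive regulator gene, rose from 57.0 ± 1.30 to 95.5 ± 1.61 CPM (log2 fold change 0.74 ± 0.04), and the pathway enzyme genes MSMO1, HMGCS1 and IDI1 rose by 0.65, 0.61 and 0.50. The median was 0.23 (camera, adjusted p = 0.0014; adjusted p = 0.163 with an estimated correlation). Glycolysis and hypoxia genes went both ways, with 7 of 26 higher and 12 lower (19 called when adjusted over the list alone) and no call for the list (median -0.09, camera, adjusted p = 0.322). ADM and NDRG1 rose by 1.06 and 0.93 and PFKP by 0.50, while lactate dehydrogenase A (LDHA) had a log2 fold change of -0.47. Among 24 housekeeping reference genes 14 were lower and 5 higher, with 19 called when adjusted over the list alone and a median of -0.21, at percentile 7.49 of matched random lists (camera, adjusted p = 0.0017; adjusted p = 0.279 with an estimated correlation). Among the lower members TUBB, VPS29 and PPIA had log2 fold changes of -0.45, -0.45 and -0.44. Of 8 nuclear-retained RNAs, included as a sign of RNA fraction, 2 were higher and 3 lower (5 called when adjusted over the list alone). MEG3 rose by 1.42, SNHG14, OIP5-AS1 and TUG1 had log2 fold changes of -0.64, -0.26 and -0.23, and the list was not called (median 0.07 with a test direction of lower, camera, adjusted p = 0.839). No gene encoded by mitochondrial DNA could be tested, since the 37 mitochondrial rows of the table held 0 counts in all.

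The 10 lowest fold changes chosen by the same rule included 6 small nucleolar RNAs, a class that guides modification of ribosomal RNA. SNORD102 fell from 5.26 ± 0.37 to 1.74 ± 0.42 CPM (log2 fold change -1.59 ± 0.16, adjusted p = 7.9e-07), and SNORD80, SNORD2, SNORD87 and SNORD110 had log2 fold changes of -1.53, -1.48, -1.28 and -1.27, and the H/ACA RNA SNORA52 of -1.36. These RNAs have no poly(A) tail and lie in introns of other genes, so their reads can also come from the host transcripts. With the gene length trend removed SNORD87 and SNORD110 no longer passed the test, at -0.31 (adjusted p = 0.075) and -0.29 (adjusted p = 0.073), and SNORD102 stood at -0.60, while over the other alternatives the adjusted p of both was at most 1.7e-05. The extracellular matrix gene ECM1 fell from 20.9 ± 0.81 to 7.51 ± 1.59 CPM (-1.48 ± 0.11), the Prader-Willi region RNA PWAR6 from 107 ± 2.92 to 41.5 ± 3.25 CPM (-1.36 ± 0.05) and the nuclear receptor cofactor gene NRIP2 from 6.78 ± 0.71 to 2.65 ± 0.40 CPM (-1.36 ± 0.14), and the cancer-testis gene MAGEB17 had a log2 fold change of -1.32 ± 0.09.

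**Figure D3:**
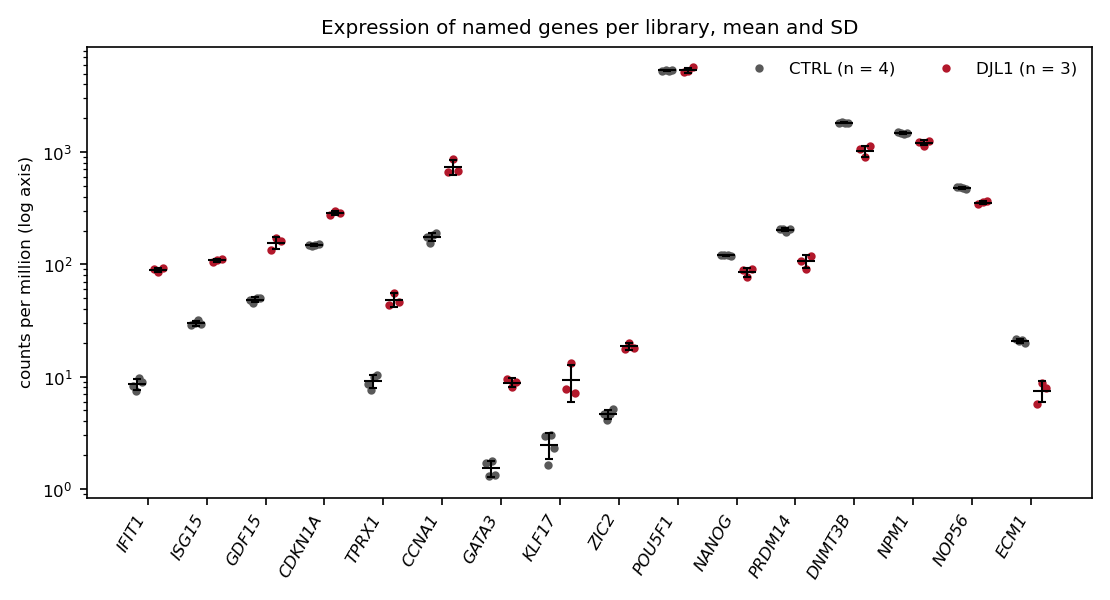
CPM on a log axis for 16 of the named genes, 1 point per library, grey for CTRL (n = 4) and red for DJL1 (n = 3), with the group mean as a bar and the SD as whiskers. The DJL1 libraries lie above all CTRL libraries from IFIT1 to ZIC2 and below them from NANOG to ECM1, and POU5F1 overlaps.

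Genes of the acrocentric chromosomes, which carry the ribosomal DNA and its distal junctions, were changed slightly less often than genes of the other autosomes. Of 3129 tested genes on chromosomes 13, 14, 15, 21 and 22, 1570 were changed (50.2%), against 11182 of 21248 (52.6%) on the other autosomes, an odds ratio of 0.907 (95% confidence interval 0.840 to 0.978, Fisher's exact test, 2-sided, p = 0.011). Among higher genes alone the odds ratio was 0.919 (Fisher's exact test, p = 0.055) and among lower genes alone 0.958 (p = 0.333), neither past the threshold. Tested one by one, none of these 5 chromosomes passed the adjustment over 23 chromosomes, and chromosome 3, with 48.2% of its genes changed, was the only chromosome that did (Fisher's exact test, adjusted p = 0.026). Neighbouring genes are not independent, so these p-values are too small.

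In the authors' deposited table of the same comparison 6545 genes were higher and 6081 lower at an adjusted p of 0.05. Among the 20189 genes tested in both, 12290 were called in both and all of these had the same direction, 333 were called in the authors' deposited table alone and 250 in the edgeR test alone. The log2 fold changes of the authors' deposited table and of the edgeR test correlated across genes with r = 0.995, a description of 1 set of libraries, since genes are not independent replicates.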

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

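The tests of sensory and defensin genes, those of heat shock and interferon genes and the removal of the gene length trend for small nucleolar RNAs were written after the results they measure were seen, and the other tests before. In 11 of 186 sets of CTRL values 1 library stood apart from the other 3 by Dixon's test, and chance gives about 1 in 20 (groups of 3 were not tested). CTRL replicate 3 had a log2 CPM of 7.60 for PRDM14 (7.68 to 7.69 in the others), 4.82 for UQCRQ (5.04 to 5.08), -1.84 for RNU6-8 (-0.67 to -0.63), -0.49 for LMX1B (-1.40 to -1.24) and 6.28 for the mean of the ribosome biogenesis factors (6.29 in the others). CTRL replicate 1 had -0.10 for H4C8 (0.31 to 0.38) and 4.93 for DPPA3 (4.79 to 4.81). CTRL replicate 2 had 6.08 for MPHOSPH8 (6.15 to 6.16) and 4.81 for BAG3 (5.13 to 5.15). CTRL replicate 4 had 2.53 for NRIP2 (2.82 to 2.85) and -2.30 for HOXA3 (-3.11 to -3.09). RNU6-8, not called with all libraries (log2 fold change -1.07, adjusted p = 0.056), passed the test without CTRL replicate 3 (adjusted p = 0.019, and 0.054 to 0.698 over the other alternatives).

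The 7 libraries were split into 4 and 3 in all 35 ways. Only the real split, 1 of 35, gave as many as 7029 higher, 6530 lower or 3364 genes changed at least 2-fold. The highest other count was 0 for each by edgeR's quasi-likelihood test. A share of 1 of 35 is the smallest that this design allows. Every other split puts libraries of both groups in at least 1 arm, which adds the group difference to the spread. The real counts thus stand apart, but this comparison cannot exclude chance for them. For the number of lists called this comparison does not exclude chance, since 6 of the 35 splits gave as many as the real 20 and the highest other split gave 20. It says little either way, because 4 of the 5 other splits put 3 CTRL libraries against the rest, which keeps the DJL1 libraries together, and the fifth moved CTRL replicate 3 with DJL1 replicates 2 and 3.

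Weakly expressed genes were higher in DJL1 as a class, with a median log2 fold change of 0.22 over 12296 tested genes under 4 CPM. The lower depth of the DJL1 libraries is argued against by thinning to equal depth, after which the median was 0.21 (0.186 to 0.227 by bootstrap over 9903 genes). That interval resamples genes, which are not independent, and does not measure the spread between libraries. The filter on low counts is argued against by the summed CPM of all genes under 4 CPM, filtered or not, which was higher in DJL1 by 0.29 on the log2 scale. Background RNA or genomic DNA stays open, since sensory and defensin genes under 1 CPM summed to 19.2 ± 0.60 CPM (SD, n = 4) in CTRL and 22.6 ± 1.77 CPM (SD, n = 3) in DJL1 (log2 ratio 0.24, exact permutation test, 2-sided, p = 0.0286, the smallest that this design allows). The 18348 genes under 4 CPM that did not pass the filter summed to 598 ± 6.86 CPM in CTRL and 836 ± 97.8 CPM in DJL1 (log2 ratio 0.48). In both sums every DJL1 library lay above every CTRL library. Against background, the 41 members of the sensory and defensin families that passed the filter had 5 higher and 6 lower. Their median was 0.11, at percentile 23.5 of random lists matched on expression (median 0.23). Having passed the filter, these 41 do not measure background in the genes below it. The medians of the trophectoderm (1.33), germ layer (1.67) and 8-cell-stage lists (2.08) lie far above both ratios. An effect of the DJL1 guides stays open as untested.

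Heat shock and interferon genes were higher in DJL1, with a median log2 fold change of 0.35 over 26 heat shock chaperone genes (18 higher, 3 lower) and of 1.92 over 23 interferon genes (23 higher). Reads shared between near-identical copies are argued against for the interferon genes, since the 20 outside the IFIT family had a median of 1.69 and all were higher. Among the heat shock genes, the HSPA1 and HSPA6 families summed to 4968 ± 1022 CPM (SD) in CTRL and 25823 ± 4188 CPM (SD) in DJL1. Reads moved among these copies would leave their sum unchanged, so the sums argue against shared reads as the source of the families' rise. The 22 heat shock genes outside these families had a median of 0.16 with 14 higher and 3 lower. This list was chosen after its values were seen, and the rise outside the families was mostly small. A single deviating DJL1 library is argued against for the heat shock and the interferon genes. The lowest median with 1 DJL1 library left out was 0.33 for the heat shock and 1.88 for the interferon genes. A difference in plasmid dose or transfection stress between the groups, which the labels do not give, and an effect of the DJL1 guides were not tested and stay open.

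Small nucleolar RNAs were lower in DJL1, with 146 of 237 lower, 0 higher by edgeR's quasi-likelihood test (0 also at an unadjusted p under 0.05, by DESeq2 and by limma-voom) and a median of -0.97. Their share of all counts was 0.0570% to 0.0597% in CTRL and 0.0291% to 0.0319% in DJL1. A fall of the host genes' own counts is argued against as the whole cause. The 125 genes that contain 222 of them had a median of -0.23, above that of their small nucleolar RNAs (-1.0) by 0.77. Counts per gene do not separate reads of introns, where these RNAs lie, so reads of unspliced host transcripts stay open. A loss of short features in the DJL1 libraries stays open, since 242 other short genes, with spans under 300 bases, had a median of -0.60. With the gene length trend removed, a trend that these short genes themselves help to set, the small nucleolar RNAs had a median of -0.12 with 26 lower and 15 higher, against 0.17 for the other short genes, and an effect of the DJL1 guides stays open as untested.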

How the results depend on the processing

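Voom with group variances, the settings on protein-coding genes and, for single genes, upper quartile factors, no filter, thinning and removal of the gene length trend were chosen after the data were seen. No called result reversed its direction among the 24 lists, under the 13 alternatives run for them, and the 126 named genes (114 in the settings on protein-coding genes). With the gene length trend removed 34 other genes changed direction, and SNORD87, SNORD110 and the pseudogene RNU6-850P were no longer called, for a cause that was not tested. Across the other tests, scalings and filters the higher genes numbered 5512 to 7275 and the lower genes 5457 to 7186. With group variances 6448 of the 7029 higher and 5601 of the 6530 lower genes were called again. Genes changed at least 2-fold went from 3364 to 1894 with the stricter filter (1659 higher, 235 lower), to 2040 in protein-coding genes alone (114 lower) and to 2034 with their GC and length trend removed (110 lower), all of which test fewer genes, and at an adjusted p under 0.01 359 were lower by at least 2-fold. With each library left out in turn the counts were 6208 to 7156 higher, 5763 to 6941 lower and 2937 to 3887 changed at least 2-fold (2476 to 3106 higher, 461 to 781 lower), the lists called 20 to 20 and the acrocentric odds ratio 0.871 to 0.928. That odds ratio was 0.919 for higher and 0.958 for lower genes alone, neither past the threshold, and the cause was not tested. With an estimated correlation camera called 0 of the 24 lists and fry 21, primitive endoderm markers being the additional one (adjusted p = 0.0056). Glycolysis and hypoxia genes were called with no filter (median -0.13, adjusted p = 0.028, and 0.073 to 0.724 over the other alternatives). The replicate numbers do not pair the samples (correlations of -0.009, -0.039 and -0.025 within numbers), and with them as a replicate block 5995 genes were higher and 5573 lower. HSPA6, called otherwise, was not called with that replicate block (log2 fold change 3.18, adjusted p = 0.0505, and up to 0.0048 over the other alternatives). EEF1A1 was called only without DJL1 replicate 3 (log2 fold change -0.08, adjusted p = 0.031) and in protein-coding genes with their GC and length trend removed (-0.09, adjusted p = 0.015), with 0.069 to 0.803 over the other alternatives. GC content was known for 76.3% of tested genes, under the 80% set for a correction over all genes, and for 96.0% of the 16676 protein-coding genes.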

Other observations

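All genes and lists in this part were chosen after their values were seen, with adjustment over the 7 lists tested. Their adjusted p-values, also those with an estimated correlation, are too favourable for that reason. They cannot be ranked against those of the lists fixed before, which were adjusted over more lists. Heat shock chaperone genes were higher in DJL1, with 18 of 26 higher, 3 lower and a median log2 fold change of 0.35 (camera, adjusted p = 9.4e-08; adjusted p = 0.032 with an estimated correlation). The inducible HSP70 genes HSPA1A and HSPA1B, which are near-identical and share reads, went from 2298 ± 479 to 11872 ± 1895 CPM (SD, n = 4 and 3) and from 2566 ± 512 to 13191 ± 2143 CPM, and the cochaperone genes DNAJB1, BAG3 and HSPH1 rose by 1.93, 1.86 and 1.57 on the log2 scale. Genes of the endoplasmic reticulum stress response had 16 of 20 higher and none lower, among them the chaperone gene HSPA5 (1.03) and HERPUD1 (1.17), with a median of 0.44 (camera, adjusted p = 7.5e-08; adjusted p = 0.028 with an estimated correlation). Targets of NF-kB had 13 of 18 higher and none lower, among them TNFAIP3 (1.66) and NFKB2 (1.37), with 1 lower at an unadjusted p under 0.05 in edgeR and 1 by limma-voom, and a median of 0.48 (camera, adjusted p = 1.7e-05; adjusted p = 0.028 with an estimated correlation). The interferon lambda gene IFNL1 rose from 0.12 ± 0.10 to 1.58 ± 0.76 CPM.

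Nuclear genes for oxidative phosphorylation were lower in DJL1, with 71 of 74 lower and none higher. ATP5MC1, a subunit of ATP synthase, fell by 0.90 on the log2 scale and UQCRQ, a subunit of complex III, by 0.77. The median was -0.46 (camera, adjusted p = 3.6e-23; adjusted p = 0.037 with an estimated correlation). Nuclear pseudogenes of mitochondrial genes, which can take reads of mitochondrial RNA, fell too, with MTCO1P12 at 5399 ± 67.4 and 1987 ± 187 CPM and MTATP6P1 at 2361 ± 48.9 and 819 ± 77.6 CPM. Of 25 tested HOX genes 24 were higher, HOXB8 by 3.56 and HOXA3 by 3.51 from very low levels, with a median of 2.34 against 0.23 for random lists matched on expression (camera, adjusted p = 1.2e-07; adjusted p = 0.028 with an estimated correlation). The patterning genes LMX1B, EN2 and PAX2 rose by 3.42, 3.28 and 3.21. Neuronal genes under the repressor REST had 21 of 28 higher and 5 lower, among them VGF (2.25) and NEFM (1.73), with a median of 0.70 (camera, adjusted p = 3.5e-06; adjusted p = 0.037 with an estimated correlation). Sensory and epithelial gene families had 5 of 41 tested members higher and 6 lower and were not called (median 0.11, camera, adjusted p = 0.998).

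The ribosomal RNA precursor genes RNA45SN1, RNA45SN2 and RNA45SN3, near-identical copies whose RNA has no poly(A) tail, had log2 fold changes of 0.53, 0.53 and 0.49, with RNA45SN1 at 166 ± 7.12 CPM in CTRL and 240 ± 17.6 CPM in DJL1. Beside the rise of RNU6-1, the U6 pseudogene RNU6-850P had a log2 fold change of -1.39, and with the gene length trend removed it was not called (-0.54, adjusted p = 0.086, and up to 0.0043 over the other alternatives). The elongation factor gene EEF1A1 stood at 8579 ± 50.4 CPM in CTRL and its pseudogene EEF1A1P5 at 3895 ± 35.6 CPM, a pair of loci with similar sequence.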
